A study of Mus musculus with 13 samples.

How the data were processed

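The deposited tables cover 13 libraries of total RNA from cerebella of mice on the C57BL/6 background, made with a modified stranded mRNA kit per the labels. Per the submitters' processing notes the reads were handled with FastQC and Trimmomatic (versions not given) and the genome build was mm9. The aligner and the program that made the tables are not given in the sources used here. For splicing the authors deposited percent inclusion (PSI) with a quality field that holds the reads for and against inclusion, and for expression they deposited cRPKM, an RPKM corrected for the mappable length of the transcript.

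All files were read as deposited. Of 22667 genes, 1114 had no value and 21553 were used, and 90 symbols belong to more than 1 gene row, which were kept apart. Of 283765 events, 30610 alternative splice site entries with no added length were left out, since each repeats the other sites of its group. Events with at least 10 reads in at least 4 libraries and a mean PSI from 1 to 99 numbered 99155. Library correlations of log2 expression were as low as 0.724, between knockout P1 library 15 and wild-type P30 library 3. Because the cRPKM values move in steps, the number of reads behind each library's table could be estimated from the step and the transcript length, which could be recovered for 94.9% of genes. Total sequencing depth is not in the files.

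Expression was tested as log2(cRPKM + 1) for genes with a mean of at least 1 cRPKM in a group (14063 genes). Splicing was tested as the log2 odds of inclusion, with 0.5 added to the reads on each side, for events with a mean PSI of 5 to 95, at least 10 reads per library and values in at least 2 libraries of each group compared. Both used limma with 1 fit of the 5 groups (8 residual degrees of freedom) and an intensity-dependent prior. P-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at adjusted p below 0.05, and an event was called when it also differed by at least 10 points of PSI. Groups of alternative splice sites counted once, by the member with the smallest p. The P1 and P10 wild-type groups hold 2 libraries each, so the prior and the other groups carry most of their estimate of spread.

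Before the data were examined, 24 gene lists, the comparisons, the tests and the alternatives were fixed. The lists were STAR family RNA-binding proteins; neuronal splicing regulators; granule cell precursor and proliferation; maturing granule cell; mature granule cell; Purkinje cell; inhibitory interneuron; Bergmann glia and astrocyte; oligodendrocyte and myelin; microglia and macrophage; endothelial and pericyte; red blood cell. The others were choroid plexus, meninges and fibroblast, midbrain and caudal hindbrain, immediate early and stress, neurexin, neuroligin and cerebellin synapse organizers, glutamate receptors and postsynaptic scaffold, GABA and glycine receptors, presynaptic release and vesicle, voltage-gated ion channels, cytoskeleton and axon guidance, genes with earlier studies of Sam68-dependent splicing, and sex-linked control genes, which were too few to test. Each list with at least 5 tested genes was tested in expression with camera of limma at its preset correlation of 0.01 and again with a correlation estimated from the libraries. The share of its genes with a called event was compared with that of other genes by Fisher's exact test, adjusted over all lists and comparisons. A microexon was an exon of at most 27 nt.

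The genes named in the text follow a rule. They are Khdrbs1, Khdrbs2 and Khdrbs3 in each comparison and up to 4 members of each list with the smallest p. They also include the 10 largest rises and 10 largest falls among called genes whose library values do not overlap between the groups compared. For splicing they are every tested Khdrbs1 event, for each earlier-studied gene its event with the smallest p, the 10 largest rises and falls among calls without overlap between the groups, and up to 3 called events per list with the smallest p. Predicted genes could be left out of the text but stayed in the counts. Some other genes that the rule takes are not reported here and also stayed in the counts. Genes and events named outside this rule are marked as chosen after their values were seen.

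In a self-test, changes of known size were added to 400 genes or events of libraries simulated with the spread of these data. The changed genes lay above about 10 cRPKM. The changed events had mid-range inclusion, and all simulated events had at least 10 reads in every library. Recovery of genes with lower expression and of other events was not measured. Of changes of 2-fold and 4-fold among 14063 genes, 49.5% and 90% were recovered for knockout against wild type at P1, 44% and 90% at P10, 38% and 95% for wild-type P10 against P1, 41% and 93% for P30 against P10, and 61% and 92.5% for knockout P10 against P1, with 12 to 16 false calls. Of PSI changes of 15 and 30 points, 0% and 27% were recovered at P1 (32682 events), 0% and 30.5% at P10 (32673 events), 0% and 17% for wild-type P10 against P1, 0.5% and 33.5% for P30 against P10 and 1.5% and 50% for knockout P10 against P1, with 0 to 7 false calls. For the effect averaged over both ages it was 81% and 94.5% of genes and 7.5% and 74% of events. Most changes of 15 points would therefore be missed, and an exon without a call is not shown to be unchanged.

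The alternatives planned were a pseudocount of 0.1, all genes with a value above 0 in at least 2 libraries, median-ratio rescaling, a fit of only the compared groups, each library left out, at least 20 reads, a mean PSI of 1 to 99, at least 15 points, no test but 15 points with a gap of 5 points between groups, introns left out where the balance p is below 0.05, PSI itself in limma, and the estimated correlation. After seeing the data, reads on each gene's exon junctions per M reads in place of cRPKM (9273 genes with at least 20 per event), libraries 12 and 15 left out, only genes with a mean of at least 10 cRPKM, only the 8 libraries with at least 1 M estimated reads, and the effect averaged over both ages were added. For Gm10479 and Hist1h2ag the limit of the read test was tightened after its values were seen: a first limit of 10 reads at the mean wild-type level had counted against too few reads, and the limit used also asks for 10 reads at the level of the lower wild-type library (13.3 for Gm10479, 9.09 for Hist1h2ag) and 3 without the deepest knockout library (5.87 and 2.53). Each gene was then held to it separately. Also after the values were seen, the explanation of the P10 relation by 1 library was made to require that it ends without exactly 1 library. Tests of whether called events and genes lie near Khdrbs1 were dropped because those calls had prompted them, and the test among uncalled genes that replaced them had its limits set before its values were seen. Coordinates are those of the deposited tables, and nothing that needs a genome sequence, such as binding motifs, was done. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.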

Results

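Sam68, the RNA-binding protein encoded by Khdrbs1, binds U/A-rich sequence in pre-mRNA and regulates the inclusion of alternative exons. To evaluate which exons and genes depend on it in the cerebellum after birth, the deposited tables of 13 RNA-seq libraries of mouse cerebellum were compared. The libraries were wild type at postnatal day 1 (P1, n = 2), P10 (n = 2) and P30 (n = 3) and Sam68 knockout at P1 (n = 3) and P10 (n = 3), with no knockout at P30. One table gave the percent inclusion (PSI) of 283765 splicing events, and the other gave the expression of 22667 genes as cRPKM, reads per kilobase of mappable transcript corrected for library size. Fold changes are differences of mean log2(cRPKM + 1). Summed over the simple exon events alone, the libraries held 7.83 to 13.66 M junction reads, where a read can count in more than 1 event. The reads behind the expression values, worked out from the spacing of the values, ranged from 0.0936 M (knockout P1, library 15) to 3.92 M (wild-type P30, library 2). These counts differ in kind, so their gap does not measure a difference in depth. In library 15, 794 genes with a mean of at least 50 junction reads were listed at 0. The Y-linked genes Kdm5d, Ddx3y and Eif2s3y were present in every library, with at least 7.17, 19.76 and 32.67 cRPKM, and Uty was listed at 0 only in library 15. The labels do not say whether libraries of a group came from separate animals, so every p-value measures only the spread between these libraries.

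Khdrbs1 had 56.45 and 74.4 cRPKM in the wild-type P1 libraries against 5.42, 4.22 and 8.5 in the knockouts, and 61.2 and 56.2 at P10 in wild type against 2.06, 1.28 and 3.59. In wild type at P30 it had 31.37, 29.5 and 36.75. The mean fell by 3.27 log2 units at P1 (65.4 ± 12.7 to 6.05 ± 2.21, SD, SE 0.31, limma adjusted p = 0.00112) and by 4.23 at P10 (58.7 ± 3.54 to 2.31 ± 1.18, SE 0.31, adjusted p = 0.000192). It kept both calls with any single library left out. No Khdrbs1 splicing event could be tested. Khdrbs2, which encodes the related protein SLM1, had 34.7 ± 4.52 cRPKM in knockout and 14 ± 0.283 in wild type at P1 (log2 fold change 1.24, SE 0.28, adjusted p = 0.536). At P10 it had 18.9 ± 5.48 and 8.24 ± 2.51 (1.10, SE 0.28, adjusted p = 0.884). Khdrbs3, which encodes SLM2, differed by 0.13 (SE 0.25, adjusted p = 0.921) and 0.46 (SE 0.25, adjusted p = 0.885). Of the 5 measured entries of the STAR family of RNA-binding proteins, 1 fell, 0 rose and 4 did not pass at either age. Adjusted over the list alone, 1 rose (Khdrbs2) and 1 fell at both ages. Qk holds 2 of the 5 entries.

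**Figure D1:**
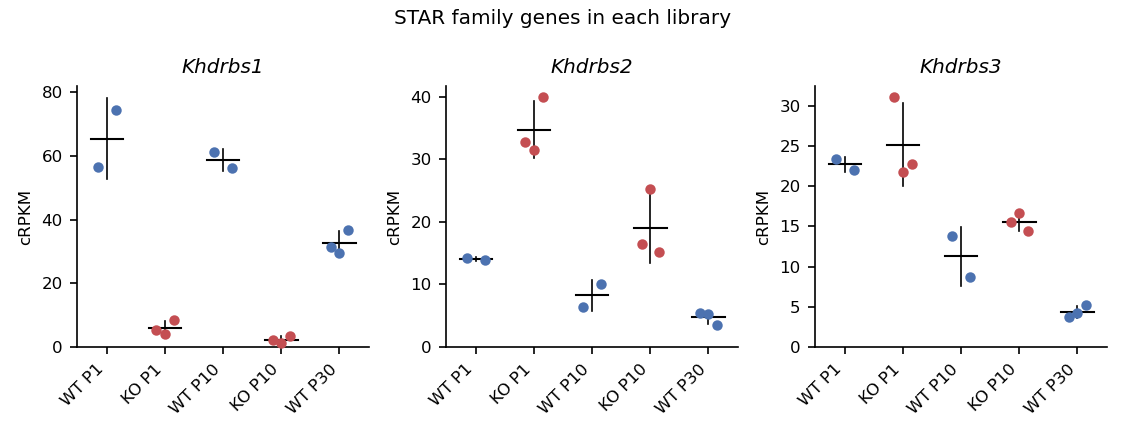
Expression of Khdrbs1, Khdrbs2 and Khdrbs3 (cRPKM, vertical axis) in the 5 groups of libraries (horizontal axis, wild type blue, knockout red). Each point is a library, the horizontal line is the group mean and the vertical line its SD.

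To ask which exons change without Sam68 at P1, splicing of the knockout (n = 3) was compared with wild type (n = 2). Inclusion rose in exons of Kif21a, a kinesin motor (108 nt, 71.4% ± 8.3 to 94.9% ± 0.5, adjusted p = 0.0217) and of Stxbp5l, the syntaxin-binding protein tomosyn 2 (171 nt, 73.0% ± 8.9 to 99.3% ± 1.2, adjusted p = 0.0185). Eif2s3y, a Y-linked translation factor gene, gained a 95 nt exon (54.7% ± 4.4 to 86.9% ± 0.7, adjusted p = 0.0467). Usage of a 3′ splice site of Rcan3, a regulator of calcineurin, fell from 85.5% ± 0.7 to 16.5% ± 0.9 (adjusted p = 0.00728). A 103 nt exon of the palmitoyltransferase gene Zdhhc18 fell from 100% in both libraries to 82.6% ± 4.1 (adjusted p = 0.00728).

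In all there were 9 calls among 37260 tested events, 7 higher and 2 lower, and 1707 events had an unadjusted p below 0.05. Among genes with earlier studies of Sam68-dependent splicing, 1 of 16 carried a called event (6.25% against 0.082% of other genes, Fisher's exact test, adjusted p = 0.0659). The shares for voltage-gated channels (1 of 30, adjusted p = 0.109), neurexin, neuroligin and cerebellin synapse organizers (1 of 40, 0.13) and cytoskeleton and axon guidance (1 of 44, 0.139) did not pass. The 27 nt exon of Sgce, a sarcoglycan gene on the Sam68 list, had 77.2% ± 3.7 in knockout and 42.8% ± 2.0 in wild type (adjusted p = 0.143). The 90 nt exon of Nrxn2 had 53.1% ± 2.5 and 40.4% ± 8.0 (adjusted p = 0.882). The count fell to 3 without wild-type library 8 or without knockout library 13, 14 or 15. Leaving out each of the 5 libraries in turn, Eif2s3y kept its call in 0 and Stxbp5l in 1. Rcan3 and Zdhhc18 lost their calls only without library 8 (adjusted p = 0.066 and 0.0507). Kif21a (adjusted p = 0.066 to 0.17) lost its call without any 1 of the 5 libraries and kept the sign of its difference.

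To ask which genes change in abundance at P1, the expression table was tested in the same way. Besides Khdrbs1, Dusp22, a dual-specificity phosphatase gene, had 7.93 and 6.88 cRPKM in wild type and was listed at 0 in the 3 knockout libraries (adjusted p = 0.00415). Hist1h2ag, a replication-dependent histone gene with near-identical copies, had 10.03 and 13.92 and was listed at 0 in the knockouts (adjusted p = 0.000314), as was the predicted gene Gm10479 (29.6 and 82.2, adjusted p = 0.000187). Tbata rose from 1.23 ± 0.0707 to 7.48 ± 0.338 cRPKM (log2 fold change 1.93, SE 0.23, adjusted p = 0.00723). These 5 calls, 1 higher and 4 lower, came from 14063 genes, of which 953 had an unadjusted p below 0.05. Counted from reads on exon junctions, the differences were −0.61 for Dusp22 (adjusted p = 0.554), −0.07 for Gm10479 (adjusted p = 0.952) and 0.37 for Tbata (adjusted p = 0.761). Without wild-type library 8, Dusp22 (adjusted p = 0.0723) and Tbata (0.057) lost their calls, as they did with only the compared groups in the fit (adjusted p = 0.647 and 0.962). The count was 8 without library 8, 42 without wild-type library 9 and 54 without knockout library 14.

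Outside the STAR family no listed gene passed at P1, so 0 rose and 0 fell in each of the other 22 tested lists. As groups, 14 lists shifted in the limma camera test with its preset correlation, and 0 did with an estimated correlation. Genes of the midbrain and caudal hindbrain, included as markers of tissue next to the cerebellum, had a median of −1.24 (16 measured, adjusted p = 6.22e-08, and adjusted p = 0.306 with an estimated correlation). Adjusted over the list alone, 8 of them fell. Their mean was 2.81 on the log2 scale in wild-type library 8 and 1.86 in library 9, against 1.8, 1.04 and 0.75 in the knockouts. Library 9 thus lay near knockout library 13. Beside them, granule cell precursor and proliferation genes had a median of 0.45 (30 measured, adjusted p = 0.000183, and adjusted p = 0.306 with an estimated correlation). This rested on wild-type library 8, whose mean of these genes was 3.89 on the log2 scale, while library 9 had 4.77 and the knockouts 4.55, 4.73 and 4.63. Bergmann glia and astrocyte genes were lower as a group (20 measured, median −0.50, adjusted p = 0.0182, and adjusted p = 0.306 with an estimated correlation). So were oligodendrocyte and myelin genes (25 measured, −0.41, adjusted p = 0.0103, and adjusted p = 0.408 with an estimated correlation). Inhibitory interneuron genes (14 measured, −0.38, adjusted p = 0.0279, and adjusted p = 0.306 with an estimated correlation) and red blood cell genes (6 measured, −1.41, adjusted p = 0.0251, and adjusted p = 0.306 with an estimated correlation) followed. Among their members, the glial GABA transporter gene Slc6a11 had 54.5 ± 14.7 cRPKM in knockout and 121 ± 41.2 in wild type. The lipid carrier gene Apoe had 792 ± 175 and 1450 ± 453, and Gpr17, a marker of oligodendrocyte progenitors, had 3.53 ± 1.3 and 11 ± 3.03. Wild-type library 9 was no higher than knockout library 14 in the mean of the Bergmann glia list (5.71 in each) or the oligodendrocyte list (2.23 and 2.33). For red blood cell genes knockout library 13 was lowest (1.57), with 4.24 and 3.34 in libraries 14 and 15 and 4.83 and 4.9 in wild type. Adjusted over the list alone, 2 Bergmann glia genes and 3 oligodendrocyte genes fell.

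Synaptic lists were lower in cRPKM as groups in the P1 knockout beside these glial and tissue-boundary markers. Depth differed with genotype: knockout libraries 13 and 15 had 0.342 and 0.0936 M estimated reads, against 1.55 and 1.12 M in wild type. Endothelial genes, for instance, were at 2.91 and 2.77 in these knockouts and 3.46 and 3.34 in wild type. Their junction reads gave 4.35 and 4.33 against 4.37 and 4.24. For synapse organizers junction reads gave 6.54 and 6.28 in wild type and 6.27, 6.15 and 6.23 in knockout. The median was −0.25 for neurexin, neuroligin and cerebellin synapse organizers (50 measured entries of 49 genes, adjusted p = 0.00793, and adjusted p = 0.306 with an estimated correlation). The median was −0.29 for GABA and glycine receptors (20 measured, adjusted p = 0.0182, and adjusted p = 0.306 with an estimated correlation). Presynaptic release and vesicle genes had −0.26 (47 measured, adjusted p = 0.0118, and adjusted p = 0.41 with an estimated correlation). Voltage-gated channels had −0.19 (37 measured, adjusted p = 0.0383, and adjusted p = 0.306 with an estimated correlation) and glutamate receptors and postsynaptic scaffolds −0.14 (40 measured, adjusted p = 0.0481, and adjusted p = 0.306 with an estimated correlation). For GABA and glycine receptors wild-type library 9 (mean 3.33) lay below knockout library 13 (3.39). The neuroligin gene Nlgn1, for instance, had 9.74 ± 2.16 cRPKM in knockout and 18.4 ± 4.78 in wild type. Purkinje cell genes (21, 0.21, adjusted p = 0.0182), meninges and fibroblast genes (18, 0.29, adjusted p = 0.00762) and maturing granule cell genes (14, 0.12, adjusted p = 0.0279) were higher as groups, each with adjusted p = 0.306 with an estimated correlation. In each of these 3 lists the mean of 1 wild-type library lay within the range of the knockouts (library 9 at 4.38 for Purkinje cells and 5.9 for maturing granule cells, library 8 at 3.77 for meninges). Reads on exon junctions gave a median of 0.04 for maturing granule cells (adjusted p = 0.832). No shift was seen for neuronal splicing regulators (30 measured, adjusted p = 0.618), the STAR family (0.618), cytoskeleton and axon guidance (45 measured, 0.618) or genes of earlier Sam68 studies (16 measured, 0.779). Nor was one seen for mature granule cells (27 measured, adjusted p = 0.276), microglia (18, 0.239), endothelial cells and pericytes (19, 0.276), choroid plexus (14, 0.368) or immediate early and stress genes (17, 0.565).

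To ask which exons depend on Sam68 at P10, knockout (n = 3) and wild type (n = 2) were compared at the later age. The Sgce 27 nt microexon at chromosome 6, 4640469 to 4640495, rose from 32.5% ± 2.0 to 75.7% ± 4.0 (adjusted p = 0.0368). The Kif21a exon rose from 64.7% ± 12 to 93.0% ± 2.5 (adjusted p = 0.0209), and the Stxbp5l exon from 77.4% ± 8.6 to 100% in every knockout library (adjusted p = 0.00759). Rbm25, a splicing regulator gene, gained a 64 nt exon (2.7% ± 0.8 to 13% ± 3.2, adjusted p = 0.0108) and Ttc17 a 549 nt exon (1.6% ± 0.4 to 12.9% ± 5.4, adjusted p = 0.0318). The Rcan3 splice site fell from 84.9% ± 6.9 to 26.1% ± 15.9 (adjusted p = 0.0119) and the Zdhhc18 exon from 99.8% ± 0.3 to 85.0% ± 4.2 (adjusted p = 0.0108). An 86 nt exon of the DNA polymerase gene Pole fell from 100% to 65.9% ± 3.2 in the 2 knockout libraries with enough reads (adjusted p = 0.0119). Also called were an intron of Layn (0% to 55.2% ± 2.7 in 2 knockout libraries, adjusted p = 0.00759) and a 111 nt exon of the ribosomal protein gene Rpl11 (83.0% ± 6.3 to 100%, adjusted p = 0.0368). Rpl11 has near-identical copies elsewhere in the genome.

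In all there were 12 calls among 38894 events, 9 higher and 3 lower, and 1735 events had an unadjusted p below 0.05. Of the genes with earlier studies of Sam68-dependent splicing, 2 of 16 carried a call (12.5% against 0.101% of other genes, Fisher's exact test, adjusted p = 0.00107). These genes had a median of 4 tested events, against 3 for other genes. The shares for synapse organizers (1 of 38, adjusted p = 0.152) and cytoskeleton and axon guidance (1 of 44, adjusted p = 0.17) did not pass. The 90 nt exon of Nrxn3 was at 95.6% ± 1.0 and 97.0% ± 0.5 (adjusted p = 1). The count was 0 without wild-type library 5, where Stxbp5l had adjusted p = 0.0754 and Sgce 0.422, and it was 6 without knockout library 11 or 12 and 0 with only the compared groups in the fit. Leaving out each of the 5 libraries in turn, Stxbp5l kept its call in 4, Rcan3, Zdhhc18, Kif21a and Rbm25 in 2, Ttc17 in 1, and Sgce and Rpl11 in 0. With 3 libraries that could be left out, Layn kept its call in 2 and Pole in 1.

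**Figure D2:**
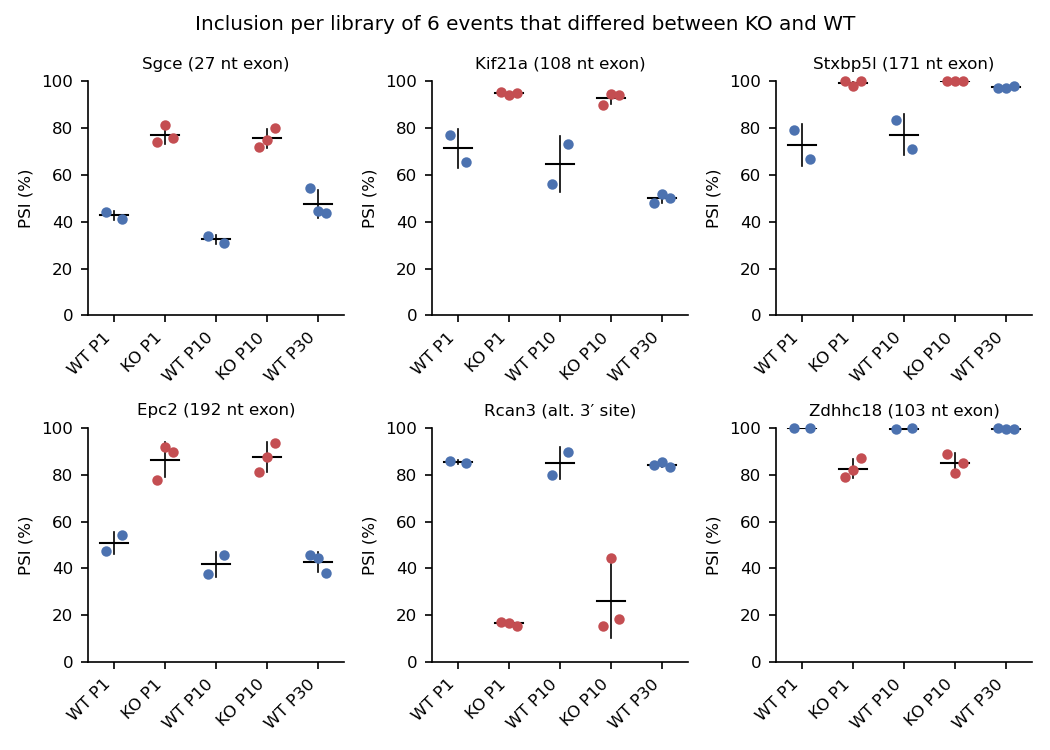
Percent inclusion (PSI, vertical axis) of 6 events in Sgce, Kif21a, Stxbp5l, Epc2, Rcan3 and Zdhhc18 in the 5 groups (horizontal axis, wild type blue, knockout red). Each point is a library, the horizontal line is the group mean and the vertical line its SD.

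To ask which genes change in abundance at P10, expression was tested at this age. Khdrbs1 alone passed, 1 of 14063 genes, and 748 had an unadjusted p below 0.05. The count was 8 without wild-type library 5, 27 without wild-type library 6 and 2 without knockout library 10. In the camera test 7 lists shifted with the preset correlation and 0 with an estimated one. Synapse organizers had a median of −0.30 (adjusted p = 1.95e-06, and adjusted p = 0.202 with an estimated correlation). Among them Nrxn3 had 11.9 ± 1.8 cRPKM in knockout and 18.2 ± 2.18 in wild type and the postsynaptic adhesion gene Lrrtm2 11.3 ± 1.33 and 17.7 ± 0.919. Voltage-gated channels had −0.29 (adjusted p = 0.000713, and adjusted p = 0.202 with an estimated correlation), with the potassium channel gene Kcna2 at 10.6 ± 5.4 and 23.6 ± 0.658. Cytoskeleton and axon guidance genes had −0.24 (adjusted p = 0.00142, and adjusted p = 0.642 with an estimated correlation), with the kinesin gene Kif1b at 73.4 ± 13 and 110 ± 24.7. Glutamate receptors and scaffolds had −0.24 (adjusted p = 0.0111, and adjusted p = 0.467 with an estimated correlation). Mature granule cell genes had −0.23 (adjusted p = 0.0142, and adjusted p = 0.642 with an estimated correlation) and presynaptic genes −0.14 (adjusted p = 0.0358, and adjusted p = 0.642 with an estimated correlation). Choroid plexus genes, markers of tissue attached to the cerebellum, had 0.57 (adjusted p = 0.00488, and adjusted p = 0.642 with an estimated correlation), with the water channel gene Aqp1 at 3.37 ± 1.36 and 0.625 ± 0.658. In 4 of these lists the mean of 1 wild-type library lay within the range of the knockouts, library 6 for mature granule cell (5.05), presynaptic (5.01) and cytoskeleton genes (4.76) and library 5 for choroid plexus (2.49). In each list other than STAR 0 rose, 0 fell and all members did not pass. Adjusted over the list alone, 1 choroid plexus gene rose and 1 GABA and glycine receptor gene fell. The other 16 lists, among them midbrain and caudal hindbrain (0.13, adjusted p = 0.441), red blood cell (0.66, 0.153), GABA and glycine receptors (−0.14, 0.153) and earlier Sam68 studies (−0.03, 0.308), did not shift.

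To ask whether the knockout acts differently at the 2 ages, the effect at P10 was tested against the effect at P1. In splicing, limma called 0 of 35785 events (925 with an unadjusted p below 0.05), so no difference in effect was shown for Sgce, Kif21a, Stxbp5l, Rcan3 or Zdhhc18. Without wild-type library 6 the count was 5, and it was 1 without wild-type library 8 or knockout library 13. In expression 2 of 14063 genes were called (728 with an unadjusted p below 0.05), Hist1h2ag (3.68, SE 0.43, adjusted p = 0.0134) and Gm10479 (5.66, SE 0.59, adjusted p = 0.00853), each listed at 0 in all P10 libraries. Leaving out 1 library gave 2 to 17 genes, with 17 without wild-type library 9, 10 without knockout library 14, 9 without wild-type library 6, 8 without library 5, 6 without library 8 and 4 without knockout library 10. Of the lists, 7 shifted with the preset correlation and 0 with an estimated one. For midbrain and caudal hindbrain genes the knockout effect was higher at P10 than at P1 (median difference of effects 1.55, adjusted p = 2.16e-06, and adjusted p = 0.508 with an estimated correlation), with 5 members that rose adjusted over the list alone. The same held for red blood cell genes (1.75, adjusted p = 0.00797, and adjusted p = 0.508 with an estimated correlation), with 3 that rose adjusted over the list alone. At P1 the mean of the midbrain and caudal hindbrain genes was 2.81 in wild-type library 8 and 1.86 in library 9, near knockout library 13 (1.8). Oligodendrocyte genes had 0.61 (adjusted p = 0.00538, and adjusted p = 0.626 with an estimated correlation) and granule precursor genes −0.54 (adjusted p = 0.000723, and adjusted p = 0.626 with an estimated correlation). Purkinje cell genes had −0.21 (adjusted p = 0.00538, and adjusted p = 0.508 with an estimated correlation). Meninges genes had −0.41 (adjusted p = 0.0317, and adjusted p = 0.626 with an estimated correlation) and cytoskeleton genes −0.17 (adjusted p = 0.00797, and adjusted p = 0.626 with an estimated correlation). No list member passed, with 1 Bergmann glia gene that rose adjusted over the list alone.

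To ask whether the same exons respond at both ages, the calls were compared between P1 and P10, contrasts that share no library. Kif21a and Stxbp5l were among 4 events called higher at both ages, where independent lists would share 0.00156. Rcan3 and Zdhhc18 were called lower at both, where independent lists would share 0.000168. Both ages come from 1 fit with a shared estimate of spread per event. The lists are thus not independent, and neither value is a chance level. All 9 events called at P1 had the same sign at P10, with a Pearson correlation of 0.98 and a Spearman correlation of 0.87 across events, which are not independent replicates. Of the 11 events called at P10 and measured at P1, 10 had the same sign (Pearson 0.92, Spearman 0.93). Across all 35618 events the Pearson correlation was 0.18.

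To use the libraries of both ages at once, the knockout effect averaged over P1 and P10 was tested (6 knockout and 4 wild-type libraries), a comparison chosen after its values were seen. Events called at single ages that passed here too included Rcan3 (−63.9 points, adjusted p = 0.000212), Zdhhc18 (−16.1, 0.000212), Stxbp5l (24.5, 0.000212), Kif21a (25.9, 0.000575) and Sgce (38.8, 0.00311). Further exons passed only here. A 192 nt exon of Epc2, a subunit of the NuA4 acetyltransferase complex, had 50.8% ± 4.9 in wild type (n = 2) and 86.4% ± 7.5 in knockout (n = 3) at P1 and 41.7% ± 5.5 and 87.6% ± 6.2 at P10 (limma adjusted p = 0.00607). A 135 nt exon of the zinc finger gene Zfp711 went from 10.8% ± 1.3 to 38.2% ± 1.5 and from 9.8% ± 1.0 to 32.8% ± 5.9 (adjusted p = 0.00512). A 36 nt exon of the glutathione-degrading enzyme gene Chac2 went from 63.8% ± 5.7 to 85.0% ± 1.0 and from 67.9% ± 1.6 to 83.3% ± 1.9 (adjusted p = 0.00898). Kif21a lost a 39 nt exon (−20.0 points, adjusted p = 0.0081) while it gained the 108 nt exon, and the synaptic scaffold gene Lrrc7 gained a 120 nt exon (19.7, adjusted p = 0.05). An intron of Pdcd4 fell by 15.1 points (adjusted p = 0.0294). The Nrxn2 90 nt exon did not pass (8.0 points, adjusted p = 0.534).

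The averaged effect called 35 of 35785 events, 26 higher and 9 lower, in 31 genes, and 27 were exons, of which 19 had a length divisible by 3. That share was not tested. At single ages such lengths were not enriched: 5 of 8 called exons at P1 (62.5% against 45.7%, Fisher's exact test, adjusted p = 0.629). At P10 they were 6 of 10 (60% against 45.6%, adjusted p = 0.633). Microexons were 0 of 8 at P1 and 1 of 10 at P10 (adjusted p = 0.531 at P10). In expression 5 genes were called lower: Khdrbs1 (−3.75, SE 0.22, adjusted p = 1.45e-05), Rcan3 (−1.22, SE 0.18, adjusted p = 0.0464), Dusp22 (adjusted p = 0.0262), Hist1h2ag (0.00891) and Gm10479 (0.00426). Hist1h2ag and Gm10479 were listed at 0 in every P10 library of both genotypes, so their averaged effect came from P1 alone. Dusp22 overlapped at P10, with 18 and 10.46 cRPKM in wild type and 6.06, 11.29 and 10.56 in knockout. Junction reads of Dusp22 and Gm10479 did not pass at P1. Rcan3 had 32.66 and 24.72 cRPKM in wild type and 8.46, 10.03 and 8.25 in knockout at P1, and 20.63 and 19.51 against 9.63, 15.38 and 7.85 at P10. The splicing count was 9 without wild-type library 5, 17 without wild-type library 8, 20 without wild-type library 9 or knockout library 14, and 23 without wild-type library 6. The expression count ran from 3 without knockout library 13 or 12 to 22 without wild-type library 9, with 18 without knockout library 14 and 13 without wild-type library 5 or 6.

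To follow normal development, wild-type P10 (n = 2) was compared with P1 (n = 2). Oligodendrocyte and myelin genes rose most: 16 of 25 measured rose, 0 fell and 9 did not pass (adjusted over the list alone 19 rose and 0 fell, median 2.23, camera adjusted p = 4.28e-20, and adjusted p = 0.0357 with an estimated correlation). The myelin basic protein gene Mbp went from 32.0 ± 10.2 to 1260 ± 170 cRPKM (log2 fold change 5.29, SE 0.52, limma adjusted p = 0.00021). Mature granule cell genes were also higher, with 11 of 27 that rose, 1 that fell and 15 that did not pass (adjusted over the list alone 14 and 1, median 0.97, adjusted p = 1.83e-15, and adjusted p = 0.0357 with an estimated correlation). Among them were the GABA-A receptor subunit gene Gabra6 (0.31 ± 0.0707 to 73.4 ± 11.8, 5.82, SE 0.53, adjusted p = 0.000133) and the cerebellin gene Cbln3 (0.925 ± 0.233 to 40.3 ± 8.68, 4.41, SE 0.34, adjusted p = 7.33e-05). Of 21 Purkinje cell genes 12 rose, 1 fell and 8 did not pass (adjusted over the list alone 13 and 2, median 1.32, adjusted p = 8.75e-09, and adjusted p = 0.0357 with an estimated correlation). The calcium-store channel gene Itpr1 rose by 2.98 (adjusted p = 0.00193) and the transcription factor gene Foxp2 fell (−2.50, adjusted p = 0.00216).

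Beside these, midbrain and caudal hindbrain genes were lower at P10: 5 of 16 fell, 0 rose and 11 did not pass (0 rose and 10 fell adjusted over the list alone, median −1.60, adjusted p = 3.33e-10, and adjusted p = 0.0903 with an estimated correlation). Meis2 went from 65.4 ± 40.3 to 1.96 ± 1.53 cRPKM (−4.44, SE 0.88, adjusted p = 0.0138). Of 20 Bergmann glia and astrocyte genes 4 rose, 2 fell and 14 did not pass (8 rose and 3 fell adjusted over the list alone, adjusted p = 0.046, and adjusted p = 0.292 with an estimated correlation). The glial filament gene Gfap rose from 8.95 ± 5.61 to 263 ± 47 (4.85, SE 0.51, adjusted p = 0.000287). Of 37 voltage-gated channels 7 rose, 3 fell and 27 did not pass (12 rose and 6 fell adjusted over the list alone, adjusted p = 0.046, and adjusted p = 0.292 with an estimated correlation). The potassium channel gene Kcna1 rose by 2.64 and the T-type calcium channel gene Cacna1h fell by 2.33.

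Of 14 maturing granule cell genes 4 rose, 1 fell and 9 did not pass (7 rose and 2 fell adjusted over the list alone, adjusted p = 0.00624, and adjusted p = 0.22 with an estimated correlation). Neurod1, a transcription factor gene of granule neurons, rose from 74.0 ± 36.5 to 428 ± 69 (2.60, SE 0.30, adjusted p = 0.000553). Of 45 cytoskeleton and axon guidance genes 1 rose, 6 fell and 38 did not pass (4 rose and 9 fell adjusted over the list alone, adjusted p = 0.046, and adjusted p = 0.562 with an estimated correlation), and the neuronal tubulin gene Tubb3 fell by 1.45. None of 18 microglia genes passed, although the list was higher as a group (median 0.78, adjusted p = 0.000977, and adjusted p = 0.147 with an estimated correlation). None of 6 red blood cell genes passed either (2 fell adjusted over the list alone, −1.44, adjusted p = 0.046, and adjusted p = 0.292 with an estimated correlation). In all 10 lists shifted, and 3 did so with an estimated correlation.

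The other lists did not shift from P1 to P10, but some held single genes that passed. Of 50 synapse organizer entries 6 rose, 2 fell and 42 did not pass (7 rose and 6 fell adjusted over the list alone). Of 40 glutamate receptor and scaffold genes 7 rose, 3 fell and 30 did not pass (10 rose and 7 fell adjusted over the list alone). Of 20 GABA and glycine receptor genes 3 rose, 2 fell and 15 did not pass (4 rose and 3 fell adjusted over the list alone), and of 47 presynaptic genes 4 rose, 4 fell and 39 did not pass (8 rose and 5 fell adjusted over the list alone). Of 30 neuronal splicing regulators 2 rose, 1 fell and 27 did not pass, and 1 of 14 inhibitory interneuron genes and 1 of 19 endothelial genes rose. Of the genes of granule cell precursors (30), choroid plexus (14), meninges (18), immediate early response (17), earlier Sam68 studies (16) and the STAR family (5) 0 passed. Adjusted over the list alone, 1 fell in each of the last 2.

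Among the splicing regulators, Rbfox3, the gene of the neuronal antigen NeuN, rose from 15.8 ± 2.3 to 61.5 ± 18.6 (1.87, SE 0.22, adjusted p = 0.000559). Mbnl2 rose by 2.06 (adjusted p = 0.00156) and Celf5 fell by 1.62 (adjusted p = 0.00269). In all 569 genes were called, 309 higher and 260 lower, and after rescaling of the libraries 573 (288 and 285). The count was 200 without wild-type library 8 and 216 without library 5.

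Exon choice moved in the same interval. The 75 nt exon of Camk2b, a synaptic kinase gene, rose from 15.4% ± 5.8 to 73.1% ± 2.7 (limma adjusted p = 3.47e-05) and the 36 nt exon of the P/Q calcium channel gene Cacna1a from 11.8% ± 2.0 to 56.5% (adjusted p = 0.000182). The Nrxn2 90 nt exon rose from 40.4% ± 8.0 to 77.9% ± 2.9 (adjusted p = 0.000694) and the 72 nt exon of the splicing regulator gene Nova1 from 34.7% ± 15.8 to 91.3% ± 1.4 (adjusted p = 0.000606). The 42 nt exon of Dlg2, which encodes the scaffold PSD-93, fell from 84.6% ± 1.8 to 20.5% ± 3.7 (adjusted p = 3.47e-05) and the 45 nt exon of the axonal adhesion gene Nfasc from 84.4% ± 0.8 to 23.5% ± 2.7 (adjusted p = 9.55e-06). The 54 nt exon of the T-type channel gene Cacna1g fell from 82.5% ± 5.9 to 30.9% ± 0.5 (adjusted p = 0.000938) and a 273 nt exon of the matrix gene Tnc from 76.1% ± 5.6 to 12.6% ± 1.3 (adjusted p = 0.00767). Of 36379 events 233 were called, 128 higher and 105 lower, in 186 genes. Microexons of at most 27 nt made up 25 of 157 called exons (15.9% against 4.79% of the other exons, odds ratio 3.76, Fisher's exact test, adjusted p = 4.19e-07). Of the 157, 125 had a length divisible by 3 (79.6% against 45.4%, adjusted p = 2.33e-17). Genes with a called event were frequent among cytoskeleton and axon guidance genes (12 of 44, 27.3% against 1.82%, adjusted p = 8.85e-10), glutamate receptors and scaffolds (8 of 36, 4.45e-06), and channels (6 of 30, 0.000179). So were they among synapse organizers (6 of 38, adjusted p = 0.000626), earlier Sam68 genes (4 of 16, 0.00123), oligodendrocyte genes (3 of 15, 0.0142) and presynaptic genes (4 of 34, 0.0198). More tested events give a gene more chances of a call. The median per gene was 6 for channels, 5 for cytoskeleton and presynaptic genes, 4.5 for glutamate receptors and 4 for earlier Sam68 genes. It was 3 for synapse organizers, 2 for oligodendrocyte genes and 3 for other genes. The count of events was 77 without wild-type library 5, 93 without library 8 and 135 without library 6.

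To follow the later step, wild-type P30 (n = 3) was compared with P10 (n = 2). Granule cell precursor and proliferation genes fell: 25 of 30, with 0 that rose and 5 that did not pass (adjusted over the list alone 0 and 26, median −3.08, camera adjusted p = 2.3e-22, and adjusted p = 0.0481 with an estimated correlation). The proliferation marker Mki67 went from 53.5 ± 20.1 to 0.153 ± 0.114 cRPKM (−5.52, SE 0.34, limma adjusted p = 2.04e-06). Maturing granule cell genes fell too, 11 of 14 with 0 that rose and 3 that did not pass (adjusted over the list alone 1 and 12, −1.37, adjusted p = 1.01e-09, and adjusted p = 0.0352 with an estimated correlation). The migrating-neuron gene Dcx fell from 113 ± 13.4 to 1.12 ± 0.638 (−5.78, SE 0.27, adjusted p = 2.71e-07). Mature granule cell genes rose, 18 of 27 with 1 that fell and 8 that did not pass (adjusted over the list alone 18 and 1, 1.72, adjusted p = 1.5e-14, and adjusted p = 0.0352 with an estimated correlation). Cbln3 rose from 40.3 ± 8.68 to 369 ± 8.63 (3.18, SE 0.31, adjusted p = 4.03e-05). Presynaptic genes had 20 that rose, 4 that fell and 23 that did not pass (adjusted over the list alone 26 and 6, 0.64, adjusted p = 1.63e-07, and adjusted p = 0.123 with an estimated correlation). The SNARE gene Snap25 rose from 337 ± 39.2 to 1670 ± 114 (2.31, SE 0.31, adjusted p = 0.000419). Of 30 neuronal splicing regulators 1 rose, 12 fell and 17 did not pass (adjusted over the list alone 1 and 18, −0.60, adjusted p = 0.000191, and adjusted p = 0.0886 with an estimated correlation). Ptbp1, a repressor of neuronal exons, fell from 65.4 ± 6.39 to 18.4 ± 2.59 (−1.78, SE 0.19, adjusted p = 6.45e-05). In the STAR family Khdrbs3 fell from 11.3 ± 3.63 to 4.37 ± 0.766 (−1.17, SE 0.25, adjusted p = 0.0076), and Khdrbs1 did not pass (−0.84, adjusted p = 0.102).

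Neuronal and glial lists also shifted from P10 to P30. Of 21 Purkinje cell genes 7 rose and 14 did not pass (7 rose adjusted over the list alone, median 0.63, adjusted p = 1.12e-05, and adjusted p = 0.0752 with an estimated correlation). Of 14 inhibitory interneuron genes 5 rose and 9 did not pass (7 rose adjusted over the list alone, 0.86, adjusted p = 0.000287, and adjusted p = 0.0862 with an estimated correlation). Of 25 oligodendrocyte genes 7 rose, 2 fell and 16 did not pass (8 rose and 2 fell adjusted over the list alone, 0.59, adjusted p = 0.0002, and adjusted p = 0.248 with an estimated correlation). Of 37 voltage-gated channels 13 rose, 4 fell and 20 did not pass (14 rose and 5 fell adjusted over the list alone, 0.54, adjusted p = 7.39e-05, and adjusted p = 0.0746 with an estimated correlation). Of 40 glutamate receptor and scaffold genes 11 rose, 3 fell and 26 did not pass (12 rose and 4 fell adjusted over the list alone, 0.22, adjusted p = 0.00236, and adjusted p = 0.123 with an estimated correlation). Of 20 GABA and glycine receptor genes 4 rose, 1 fell and 15 did not pass (5 rose and 2 fell adjusted over the list alone, 0.40, adjusted p = 0.0321, and adjusted p = 0.368 with an estimated correlation). One of 17 immediate early genes, Jun, rose (0 adjusted over the list alone, 0.59, adjusted p = 0.00476, and adjusted p = 0.199 with an estimated correlation). None of 14 choroid plexus genes passed (0.86, adjusted p = 0.0321, and adjusted p = 0.541 with an estimated correlation).

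The remaining lists did not shift from P10 to P30. Of 50 synapse organizer entries 7 rose, 7 fell and 36 did not pass (9 rose and 9 fell adjusted over the list alone), and of 45 cytoskeleton genes 2 rose, 8 fell and 35 did not pass (3 rose and 8 fell adjusted over the list alone). Of 20 Bergmann glia genes 4 rose, 5 fell and 11 did not pass (6 rose and 5 fell adjusted over the list alone), and of 18 meninges genes 1 rose, 3 fell and 14 did not pass (1 rose and 5 fell adjusted over the list alone). In the STAR family 1 fell and 4 did not pass (4 fell adjusted over the list alone). Of 16 midbrain and caudal hindbrain genes 1 rose and 1 fell, 2 of 19 endothelial genes and 2 of 16 genes of earlier Sam68 studies rose, 1 of 18 microglia genes fell and 0 of 6 red blood cell genes passed. In all 2074 genes were called, 706 higher and 1368 lower. The median ratio used for rescaling, taken over genes above 1 cRPKM in every library, shifted by −0.22. After rescaling 2005 genes were called, 1051 higher and 954 lower. Leaving out 1 library gave 1199 (wild-type library 6) to 1439 genes, with 1283 without library 5, 1263 without library 1 and 1318 without library 3.

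In splicing, some exons that had changed from P1 to P10 changed further by P30, and others changed mainly after P10. The 93 nt exon of Mapt, an alternative exon of the tau gene, rose from 37.1% ± 9.1 at P10 to 98.7% ± 0.3 (limma adjusted p = 1.09e-06) after 5.6% ± 1.6 at P1. The Cacna1a exon reached 95.1% ± 0.6 (adjusted p = 1.15e-05). The Nrxn2 exon reached 92.3% ± 1.3 (adjusted p = 0.000981). The 66 nt exon of Kifap3, on the earlier Sam68 list, was at 28.8% ± 7.7 at P1 and rose from 36.0% ± 9.8 at P10 to 78.9% ± 1.5 (adjusted p = 0.000331). The Dlg2 exon ended at 1.0% ± 0.2 (adjusted p = 7.23e-06) and the Cacna1g exon at 2.4% ± 0.8 (adjusted p = 3.43e-05). The 27 nt exon of the microtubule plus-end gene Clasp2 went from 30.2% ± 0.2 to 3.0% ± 0.8 (adjusted p = 0.000201). Grin1, the obligatory NMDA receptor subunit gene, gained a 63 nt exon (14.4% ± 0.6 to 60.0% ± 0.4, adjusted p = 1.15e-05). Bcas1, a gene of early myelinating cells, lost a 165 nt exon (80.7% ± 4.5 to 16.5% ± 0.8, adjusted p = 0.000172).

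**Figure D3:**
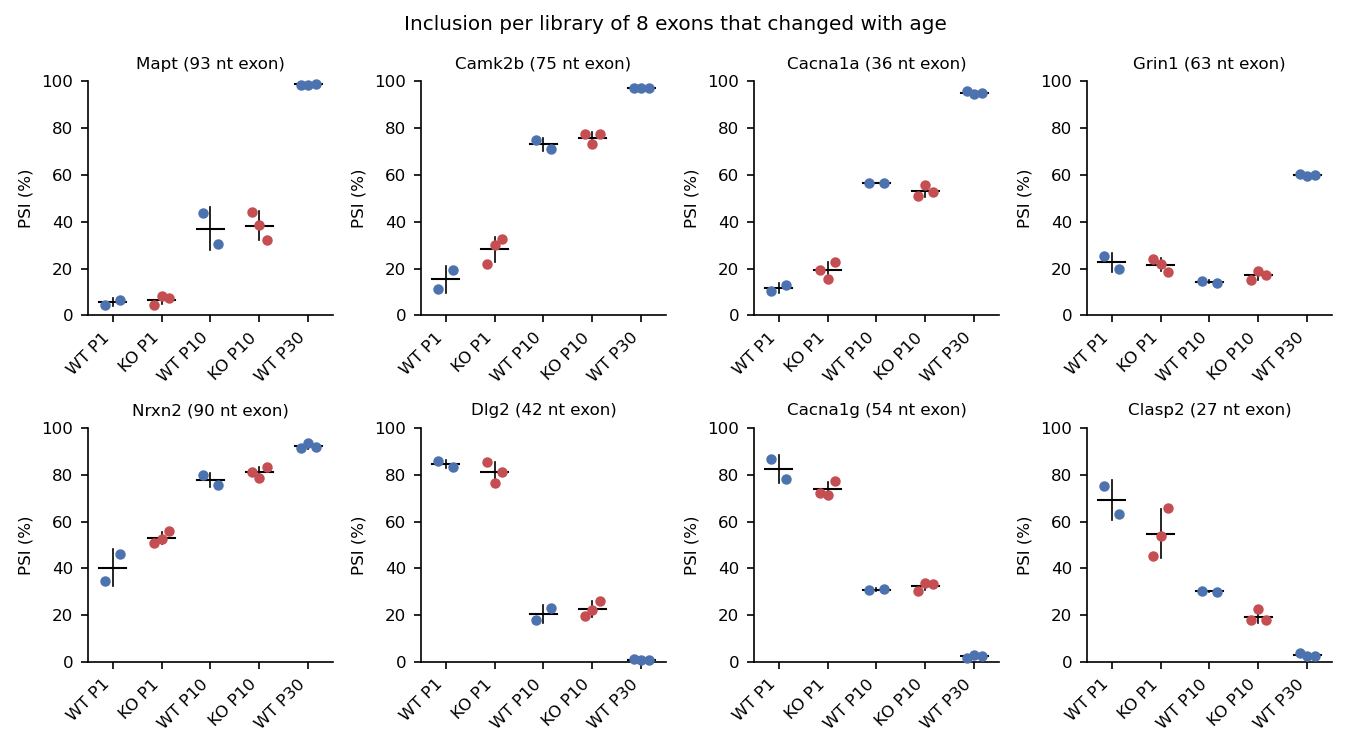
Percent inclusion (PSI, vertical axis) of 8 exons in Mapt, Camk2b, Cacna1a, Grin1, Nrxn2, Dlg2, Cacna1g and Clasp2 in the 5 groups (horizontal axis, wild type blue, knockout red). Each point is a library, the horizontal line is the group mean and the vertical line its SD.

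Between P10 and P30 1105 of 37271 events were called, 765 higher and 340 lower, in 797 genes. Microexons were 94 of 715 called exons (13.1% against 4.33%, Fisher's exact test, adjusted p = 1.98e-18). They were 82 of the 523 exons that rose (15.7%, odds ratio 4.1, adjusted p = 7.38e-21) and 12 of the 192 that fell (6.25%, adjusted p = 0.329). Of all called exons, 500 had a length divisible by 3 (69.9% against 44%, adjusted p = 4.66e-40). Called events were frequent in cytoskeleton and axon guidance genes (23 of 42, 54.8% against 8.11%, adjusted p = 5.61e-13), channels (16 of 30, 5.86e-09), and presynaptic genes (15 of 34, 4.12e-07). So were they in synapse organizers (15 of 37, adjusted p = 1.4e-06), earlier Sam68 genes (7 of 15, 46.7% against 8.26%, 0.000686), splicing regulators (9 of 27, 0.00123) and glutamate receptors and scaffolds (10 of 35, 0.00217). The cytoskeleton list had a median of 6 tested events per gene, against 3 for other genes. Presynaptic genes, glutamate receptors and splicing regulators had 5 and channels 4.5, while synapse organizers and earlier Sam68 genes had 3. The count was 366 without wild-type library 6, 698 without library 5 and 689 without library 3.

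To ask whether development proceeds without Sam68, knockout P10 (n = 3) was compared with knockout P1 (n = 3). Oligodendrocyte and myelin genes rose, 20 of 25 with 0 that fell and 5 that did not pass (adjusted over the list alone 21 and 1, median 2.63, camera adjusted p = 1.17e-20, and adjusted p = 0.0666 with an estimated correlation). Mbp rose from 12.8 ± 8.04 to 1660 ± 572 cRPKM (7.06, SE 0.43, limma adjusted p = 2.88e-06). Mature granule cell genes had 14 that rose, 1 that fell and 12 that did not pass (adjusted over the list alone 20 and 2, 1.49, adjusted p = 1.17e-11, and adjusted p = 0.0666 with an estimated correlation). Cbln3 rose from 2.14 ± 0.454 to 36.1 ± 14.3 (3.48, adjusted p = 2.25e-05). Of 45 cytoskeleton and axon guidance genes 4 rose, 16 fell and 25 did not pass (6 rose and 24 fell adjusted over the list alone, −0.45, adjusted p = 4.12e-05, and adjusted p = 0.294 with an estimated correlation). Of 21 Purkinje cell genes 10 rose, 2 fell and 9 did not pass (11 rose and 2 fell adjusted over the list alone, 0.71, adjusted p = 0.00127, and adjusted p = 0.259 with an estimated correlation). Of 18 meninges genes 3 fell and 15 did not pass (4 fell adjusted over the list alone, −0.82, adjusted p = 0.00403, and adjusted p = 0.316 with an estimated correlation). Of 18 microglia genes 4 rose and 14 did not pass (8 rose and 1 fell adjusted over the list alone, 0.80, adjusted p = 0.017, and adjusted p = 0.294 with an estimated correlation). Of 20 Bergmann glia genes 7 rose, 2 fell and 11 did not pass (7 rose and 3 fell adjusted over the list alone, 0.39, adjusted p = 0.0266, and adjusted p = 0.294 with an estimated correlation). Of 14 choroid plexus genes 1 rose and 13 did not pass (2 rose adjusted over the list alone, 1.15, adjusted p = 0.0266, and adjusted p = 0.582 with an estimated correlation). In the STAR family 2 fell and 3 did not pass (3 fell adjusted over the list alone, −0.65, adjusted p = 0.0179, and adjusted p = 0.169 with an estimated correlation). The other 14 lists did not shift. Khdrbs2 fell in the knockout from 34.7 ± 4.52 to 18.9 ± 5.48 (−0.87, SE 0.25, adjusted p = 0.046), as did the residual Khdrbs1 signal (−1.10, adjusted p = 0.0286). In all 1430 genes were called, 785 higher and 645 lower, with 886 without knockout library 10 or without library 11.

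In the knockout the Camk2b exon rose from 28.3% ± 5.5 to 76.0% ± 2.5 (limma adjusted p = 2.84e-05) and the Nrxn2 exon from 53.1% ± 2.5 to 81.1% ± 2.4 (adjusted p = 0.000463). The Mapt exon rose from 6.8% ± 1.9 to 38.4% ± 6.2 (adjusted p = 0.00024) and a 33 nt exon of Mbp from 25.5% ± 11 to 88.4% ± 4.6 (adjusted p = 5.52e-05). The Dlg2 exon fell from 81.2% ± 4.5 to 22.6% ± 3.3 (adjusted p = 8.3e-06) and the Nfasc exon from 82.8% ± 1.8 to 22.9% ± 2.4 (adjusted p = 5.33e-07). Of 38510 events 329 were called, 171 higher and 158 lower, in 254 genes. Microexons were 36 of 201 called exons (17.9% against 4.57%, Fisher's exact test, adjusted p = 1.74e-11), and 153 had a length divisible by 3 (76.1% against 44.9%, adjusted p = 4.49e-18). By list, called events were frequent in cytoskeleton genes (16 of 44, adjusted p = 5.61e-13), glutamate receptors (11 of 37, 2.75e-08), and earlier Sam68 genes (6 of 16, 2.14e-05). So were they in synapse organizers (8 of 40, adjusted p = 7.1e-05), channels (7 of 31, 0.000106), oligodendrocyte genes (5 of 15, 0.000221) and presynaptic genes (6 of 34, 0.00123). Median tested events per gene were 6 for channels, 5 for cytoskeleton and presynaptic genes and 4 for glutamate receptors and earlier Sam68 genes. They were 3 for synapse organizers, 2 for oligodendrocyte genes and 3 for other genes. The count was 180 without knockout library 10, 200 without library 13, 204 without library 11 and 516 without library 12.

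Events and genes called in wild-type development mostly moved the same way in knockout. Of the 232 events called in wild type from P1 to P10 and measured in the knockout, 228 (98.3%) had the same sign in the knockout, with a Pearson correlation of 0.96 and a slope of 0.83 across events, which are not independent replicates. Dlg2, Nfasc, Camk2b, Mapt and Nrxn2 were among those called in both, and the shared calls were 74 higher (0.597 expected of independent lists) and 67 lower (0.436 expected). The lists come from 1 fit with a shared estimate of spread, so they are not independent. Of the 569 genes called in wild type, 98.6% had the same sign (Pearson 0.93, slope 0.82 across genes), with 256 higher in both (17.2 expected) and 194 lower (11.9 expected). Selected by a call in the knockout, the slopes were 1.01 across 316 events and 1.06 across 1430 genes. A slope below 1 therefore depends on which call selects and does not show a weaker change in the knockout. Without selection by a call the relation was weaker, with the same sign in 67.7% of the 35618 events tested in both (Pearson 0.56) and in 65.9% of the 14063 genes (Pearson 0.51).

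To ask how the knockout effect lies along development, it was compared with the change of the other wild-type groups. The Stxbp5l exon was higher in knockout at P1 (99.3% ± 1.2, n = 3) than in wild type at P1 and was at 97.5% ± 0.5 (n = 3) in wild type at P30. The Kif21a exon, also higher in knockout, was at 50% ± 1.9 in wild type at P30. Across the 3441 events that changed in wild type from P1 to P30, the knockout effect at P10 had a Pearson correlation of −0.30 and a Spearman correlation of −0.29 with the change, and 34.3% had the same sign. Across genes the Pearson correlation was −0.15 (3575 genes, 44.1%). The correlation across events was −0.03 without wild-type library 5 and −0.01 without knockout library 12. For the effect at P1 and the change from P10 to P30 it was −0.14 across 1063 events and −0.32 across 2074 genes. Across the 11 measured events called at P10, the effect at P10 had a Pearson correlation of −0.07 with the change from P1 to P30.

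**Figure D4:**
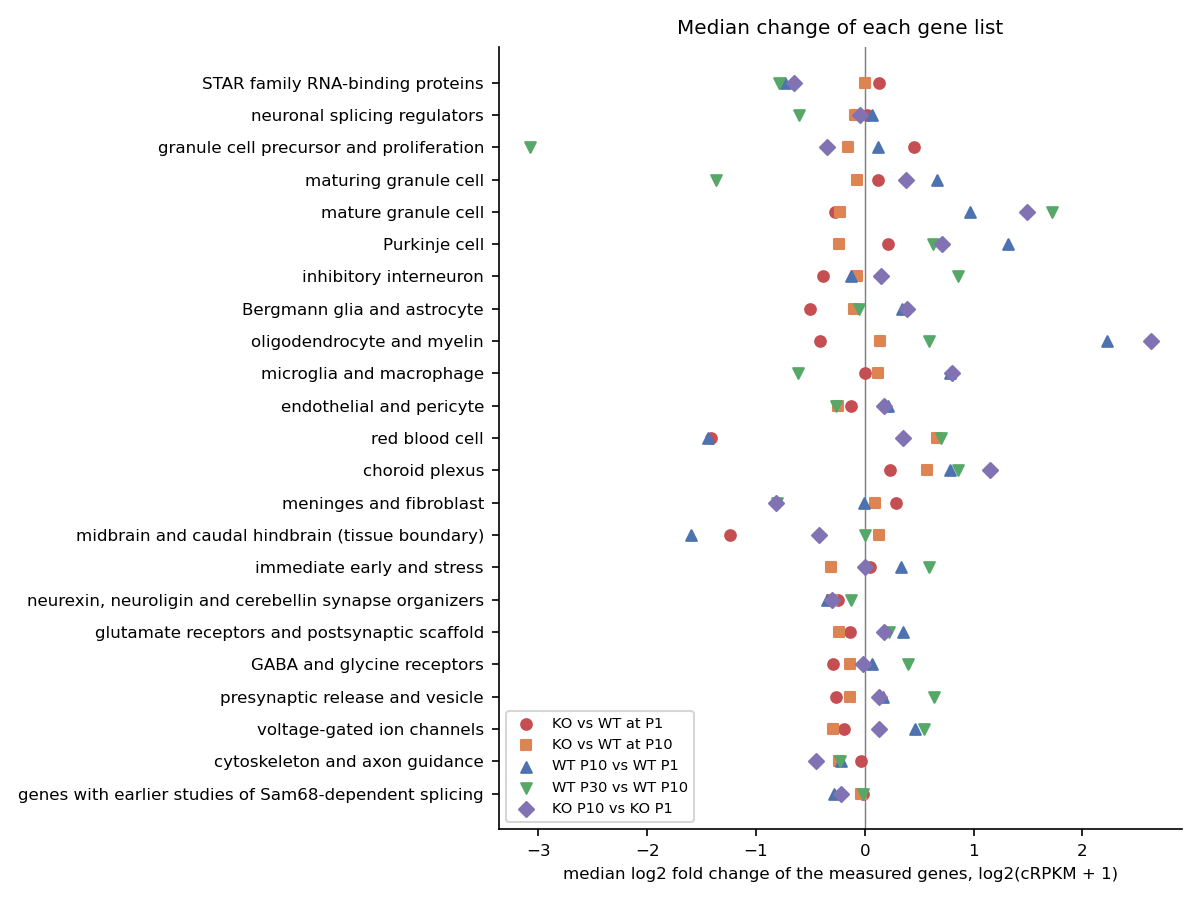
Median log2 fold change of log2(cRPKM + 1) (horizontal axis) for the members of 23 gene lists (vertical axis). Each marker is a comparison: red circle, knockout against wild type at P1; orange square, the same at P10; blue upward triangle, wild-type P10 against P1; green downward triangle, wild-type P30 against P10; purple diamond, knockout P10 against P1.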

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

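The tests of explanations in this part were chosen only after the results were seen. Hist1h2ag (3.68, SE 0.43; limma adjusted p = 0.0134) and Gm10479 (5.66, SE 0.59; adjusted p = 0.00853) stood out because the test of the knockout effect at P10 against that at P1 found a difference between the ages.

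For these 2 genes the wild-type P1 libraries had values and every knockout P1 and every P10 library was listed at 0. The reads on the junctions of Gm10479 did not follow (log2 fold change of −0.07 at P1), so the 0 of its cRPKM might come from how reads were assigned to this gene and not from its abundance. At the level of the lower wild-type library 13.3 reads of Gm10479 would be expected over the 3 knockout P1 libraries. At the mean wild-type level 5.87 would be expected without the deepest of them. Both values passed the limit, but they use the full transcript length. A shorter mappable length, which is not known, would lower them, so too few reads is not excluded for Gm10479. For Hist1h2ag, with 9.09 and 2.53, which did not pass the limit, too few reads also stays open. So does whether this gene with near-identical copies differs in abundance.

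Several knockout differences lay close to Khdrbs1 on chromosome 4, with 3 of 35 events called in the averaged effect within 10 Mb, Zdhhc18 (3.75 Mb away) and Rcan3 (5.56 Mb) among them, and 3 of 8 genes called from junction reads, Hdac1, Fuca1 and Rpl11. These calls prompted the hypothesis, and so do not test it, that a segment of another strain's chromosome 4, carried along with the disrupted gene, could set such differences without any action of Sam68. Among genes without a call, an unadjusted p below 0.05 was more frequent within 10 Mb than elsewhere for 1 event per gene (14.8% against 7.57%; Fisher's exact p = 0.0016), as a segment would give, but in junction reads the shares did not differ past the threshold (21% against 16.8%; p = 0.163). A segment that acts only on its own genes does not account for the rest, since the events called on other chromosomes, with Sgce, Kif21a, Stxbp5l and Epc2 among them, lay on 15 chromosomes, but one that acts on them through a regulator inside it was not tested and stays open. Sequence variants in the reads of Rcan3 and Zdhhc18, which the tables do not hold, would test it.

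The knockout effect at P10 ran against the change of wild type from P1 to P30 across events (Pearson −0.30). A delay of the knockout cerebellum is 1 hypothesis, and a single library that looks younger than its group is another. The correlation was −0.01 without knockout library 12 and −0.03 without wild-type library 5, so the relation needs both libraries. Neither a delay shared by all knockout libraries nor a single library was shown to account for it. In junction reads, library 5 had the highest mean of mature granule cell genes at P10 (6.93) and library 12 the lowest (6.29). Wild-type library 6 had 6.6, and knockout libraries 10 and 11 had 6.65 and 6.66. Across the 11 measured events called at P10 the Pearson correlation was −0.07. Of 7 events called in the averaged effect that also changed in wild type from P1 to P30, 2 moved against that change. The averaged effect and that change share the wild-type P1 libraries. Mature granule cell genes had adjusted p = 0.642 with an estimated correlation in the knockout at P10, so for them a smaller share of these cells and no change cannot be told apart.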

How the results depend on the processing

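The P1 and P10 wild-type groups hold 2 libraries, so with 1 left out the remaining library was assumed to vary like the other groups. No paired analysis was possible because no library number is shared by groups. Of 208 recomputed counts 109 stayed within 1.5 times and 99 moved, and the cause was not tested. Settings marked added were chosen after seeing the data. With at least 1 M reads knockout P1 (library 14), knockout P10 (10) and wild-type P10 (6) held 1 library each, so knockout P10 against P1 was 1 library against 1, and these counts do not show that better-covered libraries give more or fewer calls. Knockout against wild type at P1 in expression (5): 11 with no filter, and added 2 from junction reads, 3 with at least 10 cRPKM, 35 with at least 1 M reads. At P1 in splicing (9): 4 with PSI 1 to 99, 639 with no test, 4 with only the compared groups. At P10 in expression (1): 2 with no filter, 3 with only the compared groups, added 21 with at least 1 M reads. At P10 in splicing (12): 7, 769 and 0 for those splicing settings, added 2 without libraries 12 and 15. Interaction in expression (2): 0 with only the compared groups, added 0 from junction reads, 1 without libraries 12 and 15, 0 with at least 10 cRPKM and 26 with at least 1 M reads. Wild-type P10 against P1: 2049 genes from junction reads (569), and of 233 events 101 with PSI 1 to 99, 353 with PSI itself, 2453 with no test and 62 with only the compared groups. Wild-type P30 against P10: of 2074 genes 3864 with only the compared groups and 4216 from junction reads, and of 1105 events 614 with PSI 1 to 99 and 2626 with no test. Knockout P10 against P1: of 1430 genes 366 with only the compared groups, 2961 from junction reads and 349 with at least 1 M reads, and of 329 events 175 with PSI 1 to 99, 1105 with no test and 120 with only the compared groups. Averaged effect (added): of 5 genes 1 with only the compared groups, 8 from junction reads, 1 with at least 10 cRPKM and 31 with at least 1 M reads, and of 35 events 16 with PSI 1 to 99, 58 with PSI itself and 23 with only the compared groups. Lists that shifted with an estimated correlation were 0 of 14, 0 of 7, 0 of 7 (interaction), 3 of 10 (5 from junction reads), 3 of 13 and 0 of 9.

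With each library left out the counts ran, lowest to highest, for expression and then splicing, from 5 to 54 and 3 to 11 at P1, 1 to 27 and 0 to 13 at P10, 2 to 17 and 0 to 5 for the interaction, 200 to 440 and 77 to 212 for wild-type P10 against P1, 1199 to 1439 and 366 to 851 for P30 against P10, 886 to 1786 and 180 to 516 for knockout P10 against P1, and 3 to 22 and 9 to 33 for the averaged effect. Directions that turned, none of them called: at P1 Tpm3 (−0.03 to 6.65, lowest without wild-type library 8), Khdrbs3 (−0.03 to 0.22, lowest without knockout library 13; −0.06 with at least 1 M reads) and, with at least 1 M reads, Pvalb (0.03) and Hba-a1 (0.76); in the interaction Khdrbs2 (−0.42 to 0.14, highest without wild-type library 6; 0.00 without knockout library 12; 0.10 without libraries 12 and 15); and from P1 to P10 in wild type Khdrbs1 (−0.34 to 0.05, highest without library 9).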

Other observations

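Reads on exon junctions, chosen as a second measure of expression after the values were seen, gave 8 genes for the knockout effect averaged over both ages, 6 higher and 2 lower, of 9273. Khdrbs2 was among them (log2 fold change 1.03, SE 0.13; limma adjusted p = 0.0014), with 81.7 and 68.0 junction reads per M in wild type at P1 and 181.4, 128.1 and 148.1 in knockout, and 48.0 and 50.3 against 93.3, 119.5 and 94.6 at P10. A hypothesis is that the related protein SLM1 is raised when Sam68 is missing, which may fill part of its role at exons such as that of Nrxn2, at 8.0 points (adjusted p = 0.534). From cRPKM the test at P1 gave 1.24 and did not pass (adjusted p = 0.536).

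Hdac1, a histone deacetylase gene −0.219 Mb from Khdrbs1 and chosen after its values were seen, fell by 2.37 in junction reads (SE 0.15; limma adjusted p = 3.73e-07), from 38.5 and 45.4 per M in wild type to 6, 7.2 and 6 in knockout at P1 and from 29.7 and 31.7 to 8.3, 8.2 and 6.4 at P10. Its cRPKM varied widely within groups, with 17.55 and 34.8 in wild type and 57.58, 16.37 and 126.37 in knockout at P1, and 113.8 and 49.57 in wild type and 79.1, 57.06 and 40.04 in knockout at P10, and passed at neither age (log2 fold change 0.97, adjusted p = 0.746, and −0.40, adjusted p = 0.97). Fuca1, a lysosomal enzyme gene, rose by 0.87 (SE 0.12; adjusted p = 0.00732), and Rpl11 by 2.29 (SE 0.26; adjusted p = 0.00103) and Rps27l by 1.71 (adjusted p = 0.0423), both with near-identical copies elsewhere. In wild-type development an intron of Itsn1, an endocytic scaffold gene, was retained at P10 only, with 5.3% ± 0.2 at P1, 57.5% ± 4.0 at P10 (limma adjusted p = 0.000148) and 1.2% ± 0.5 at P30 (adjusted p = 1.7e-06).

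The limits for splits of the libraries were written after the real counts were seen and before any other split was counted, and the effect averaged over both ages was itself chosen after the results of each age were seen. Of the 10 ways to divide the 6 knockout libraries into 3 and 3, only the real one, 1 of 10, gave as many genes (1430, highest other 17) and only 1 gave as many events (329, highest other 86). The splits are too few for a share under 0.05. For the effect averaged over both ages, 2 of 100 splits of each age's libraries gave as many events (35, highest other 137), and the other split set wild-type P1 library 8, knockout P1 library 15, wild-type P10 library 6 and knockout P10 library 12 against the rest. These 4 libraries may thus share a difference in splicing other than genotype. For expression 15 of 100 splits gave as many genes (5, highest other 59), so apart from Khdrbs1 the 5 genes are no more than other divisions of the libraries give. Every split with 8 or more genes, with 59, 54 and 34 the highest, set knockout P1 libraries 13 and 15 on the same side. These 2 had the fewest estimated reads behind cRPKM at P1 (0.342 and 0.0936 M), so those splits also divide the P1 libraries by depth. In the splits with 59, 54 and 34 genes the P10 libraries set with them came from libraries 5, 11 and 12. These had the fewest estimated reads at P10 (0.346, 0.414 and 0.295 M). The 15 of 100 is thus not a share of chance divisions alone.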
